A study of Mus musculus with 12 samples.

How the data were processed

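Total RNA of mouse embryonic fibroblasts, wild type (WT) or lacking Gdap1 (KO), was labelled from the whole transcript with biotin and hybridised to 1-colour Affymetrix arrays. Cells were collected before reprogramming (day 0) or at day 4, with 3 arrays in each of 4 groups and 12 arrays in all. The treatment label, common to all arrays, describes overnight transduction with the 4 factors or a mock transduction and further growth, and does not say which of these the day 0 cells had. The values deposited by the authors are log2 probe-set levels, 1 column per array, between 1.33 and 13.35. The submitters' processing notes name Affymetrix Expression Console without a version, and the background correction, normalization and summary method are not given in the sources used here. Medians and quartiles were nearly equal across the 12 arrays, and no further normalization was applied. For arrays no count or depth exists, and their number limits the precision.

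The table held 41345 probe sets, of which 23521 had 1 gene symbol, 1814 had several and 16010 had none. A gene was represented by its probe set with the highest mean over all 12 arrays, which mattered for 1082 genes with more than 1 probe set, and 22180 genes were tested. Probe sets without a single symbol were left out of the comparisons and tested apart. Of the symbols, 99.82% were found in a RefSeq gene table. No filter on low levels was used. The table held 0 columns of other samples.

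The groups were compared with limma 3.58.1 in R 4.3.3. One linear model with 4 group means and no covariate was fitted to all 12 arrays, which left 8 residual degrees of freedom, with 4.56 more from the empirical Bayes prior. The 5 comparisons were WT day 4 against WT day 0, KO day 4 against KO day 0, KO against WT at day 0, KO against WT at day 4, and the difference of the day 4 changes, KO minus WT. The moderated tests of limma were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of changes are standard errors of the model, and each change rests on n = 3 arrays per group. A minimum of a 2-fold change was counted as an alternative. Correlations between comparisons run across genes, share no arrays, and carry no p, because genes are not independent replicates.

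A set of 34 gene lists with 1142 members, of which 1050 were measured, was tested with limma's camera at its preset correlation of 0.01. Its p-values were adjusted over 170 tests, the 34 lists in the 5 comparisons, and the tests were repeated with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone. Per-array list values are means of the members, each centred over the 12 arrays. The lists, the model, the comparisons, the alternatives and the rule for naming genes were chosen before the data were examined. List members were matched to symbols directly or through an older name. After list results had been seen, the matching was corrected so that a name that is itself a gene's symbol is never read as a synonym of another gene, which removed a wrongly matched member from each of 3 fixed lists: the fibroblast, inflammatory and glycolysis lists. The first matching is reported as an alternative, and with it the glycolysis list in KO day 4 against KO day 0 did not pass (adjusted p = 0.0541, against 0.0244).

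The genes named were Gdap1 and the 4 transduced factors, and in each comparison the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups, a condition dropped for the difference of changes. Predicted and clone names, small RNAs, pseudogenes and olfactory or vomeronasal receptors were left out of these. For each list described, up to 4 members past the threshold with the smallest p were eligible, or the 2 with the smallest p where none passed, and all of those past it where 5 or fewer passed. Of the 5 sex markers of the rule, 4 were measured. Genes of lists assembled later are named as such.

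The model was tested on simulated changes added to noise of the size seen in these arrays. At a 1.5-, 2- and 4-fold change it recovered 68.7%, 91% and 100% of the changed genes for WT day 4 against WT day 0, with 13 false calls among 186. For KO against WT at day 0 these were 59.7%, 94% and 100% (9 false among 178). For the difference of changes they were 38.8%, 82.1% and 95.5% (2 false among 146). Unequal arrays, correlated genes and many changed genes were not simulated, so these rates need not hold here.

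The alternatives were a filter on genes under the 25th percentile of levels, quantile normalization, centring on array medians, the average of a gene's probe sets, all probe sets of the table, a trended and robust prior, array weights, fits to the compared groups alone, the replicate number as a block, a 2-fold minimum, an estimated correlation in camera, and the omission of each array in turn. Leaving out WT day 4 array 1 together with KO day 4 array 2, and matching list members through any synonym, were chosen after seeing the data. Where an omission left 2 arrays in a group, the spread was pooled over the groups. Other splits of the samples were counted for the 5 comparisons, all 10 splits of 3 against 3 where a pair of groups was compared and 100 drawn with a fixed seed for the difference of changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.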

Results

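Mouse embryonic fibroblasts, connective-tissue cells grown out of embryos, were profiled on 1-colour Affymetrix arrays to ask whether loss of Gdap1 changes gene expression early in reprogramming. Gdap1 encodes a protein of the outer mitochondrial membrane that takes part in mitochondrial fission. Reprogramming meant transduction with Pou5f1 (Oct4), Sox2, Klf4 and Myc, 4 transcription factors that can turn fibroblasts into induced pluripotent stem cells. The 12 arrays formed 4 groups of 3: wild-type (WT) cells before reprogramming (day 0), WT cells at day 4, and Gdap1-null (KO) cells on the same days. Each array gave a log2 level for 41345 probe sets, from which 22180 genes were tested. Array medians over all genes lay between 4.68 and 4.72. The median SD of a gene within its group (n = 3) was 0.09 for WT day 0, 0.13 for WT day 4, 0.09 for KO day 0 and 0.12 for KO day 4. WT day 4 array 1 had the lowest mean Pearson correlation with its own group across genes, 0.987, followed by WT day 4 array 3 (0.991), WT day 4 array 2 (0.991) and KO day 4 array 2 (0.993). The labels do not say whether the arrays of a group come from separate cultures or animals, so every p-value measures only the spread between these samples. No batch is named either, so batch and group cannot be told apart, and the number of arrays limits the precision.

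Gdap1 itself gave levels of 3.30, 3.24 and 3.04 in the WT day 0 arrays and 2.82, 3.02 and 3.15 in the WT day 4 arrays. In the KO arrays it gave 3.10, 2.97 and 3.28 at day 0 and 3.21, 2.98 and 3.28 at day 4. KO minus WT was -0.08 ± 0.12 (SE, n = 3 per group, adjusted p = 0.831) at day 0 and 0.16 ± 0.12 (adjusted p = 0.395) at day 4. Its probe set lay at the 14.1 percentile of all genes, under the level of 3.75 that marks the 25th percentile, and a probe set so near the floor checks nothing about the genotype. Of the 4 transduced factors, Klf4 rose at day 4 by 2.94 ± 0.09 (SE, n = 3 per group, adjusted p = 9.02e-10) in WT cells and by 3.28 ± 0.09 (adjusted p = 2.92e-10) in KO cells. Myc fell by 1.02 and by 0.94 on the log2 scale (adjusted p = 3.06e-06 and 4.92e-06). Pou5f1 changed past the threshold in KO cells alone (0.38 ± 0.09, adjusted p = 0.00541, against 0.10 ± 0.09, adjusted p = 0.516, in WT cells), and its difference of changes did not pass (0.28 ± 0.13, adjusted p = 0.242). Sox2 did not pass in WT cells (0.19 ± 0.12, adjusted p = 0.338) or in KO cells (-0.10 ± 0.12, adjusted p = 0.599). The species of the transduced sequences, and whether these probe sets read them, are not given in the sources used here.

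**Figure D1:**
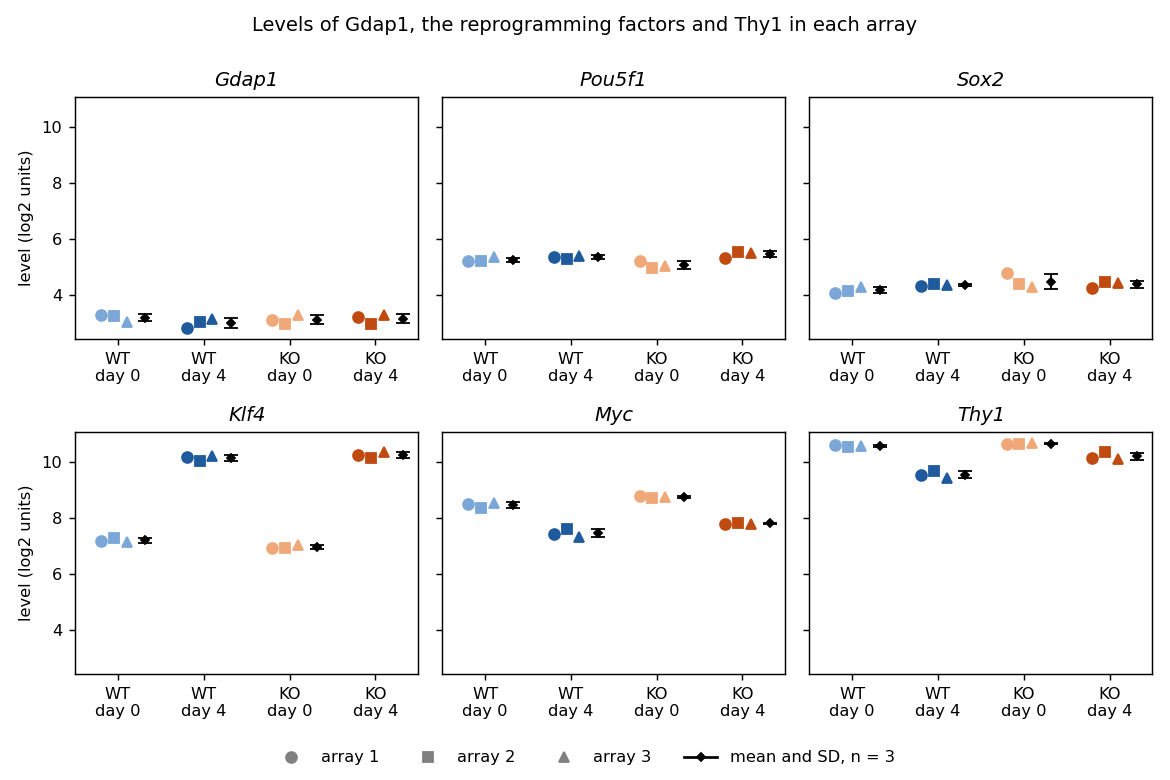
Log2 level (y axis) of Gdap1, the 4 transduced factors and Thy1 in each array (points) by group (x axis), with the group mean and SD (n = 3). Klf4 lay between 10.04 and 10.38 in the 6 day 4 arrays and between 6.94 and 7.31 in the 6 day 0 arrays, while Gdap1 stayed between 2.82 and 3.30 in all 12.

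The change from day 0 to day 4 in WT cells holds reprogramming together with transduction and time in culture, which these groups do not separate. Contractile genes fell: Cnn1, which encodes calponin of smooth muscle, decreased by 3.98 ± 0.43 on the log2 scale (SE, n = 3 per group, 15.8-fold, adjusted p = 2.5e-05), Ankrd1 by 3.41 ± 0.14 (adjusted p = 2.37e-08) and Actg2, a smooth muscle actin, by 2.77 ± 0.32 (adjusted p = 4.52e-05). Ceacam1, a cell adhesion molecule, rose 32.6-fold (5.03 ± 0.23, adjusted p = 4.78e-08), and the steroid-metabolising Akr1c18 rose 25.5-fold (4.67 ± 0.09, adjusted p = 1.15e-11). Other large rises were those of Sostdc1 (4.38 ± 0.23), Aldh3a1 (4.17 ± 0.37), Vsnl1 (4.15 ± 0.31), Tek (4.08 ± 0.17), Crym (3.84 ± 0.29), Slurp1 (3.81 ± 0.18) and Sbspon (3.67 ± 0.23). Saa3, an acute-phase protein gene, rose by 3.83 ± 1.06 (adjusted p = 0.0188), a call lost without WT day 0 array 1 (adjusted p = 0.0551) or array 2 (0.0569). It was also lost with a trended robust prior (0.0714) and in a fit to these 2 groups alone (0.082), and without WT day 4 array 1 the rise of Saa3 was 1.97. The remaining largest falls were in Lrrc15, Gjb2, Ptprn, Trav9d-3, Ppbp, Map3k7cl and Fhl5, between -3.88 and -2.91. In all, 5072 genes passed, 2469 higher and 2603 lower, of which 421 rose and 358 fell at least 2-fold. The higher genes outnumbered the lower ones with array weights (2776 and 2708) and without WT day 4 array 1 (2644 and 2463).

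Of the 34 gene lists, 14 shifted in WT cells, 3 up and 11 down. No list kept a call with an estimated correlation in camera, where 8 lists had an unadjusted p under 0.05. All 23 members of the actin cytoskeleton and smooth muscle list were lower, and 23 were lower adjusted over the list alone, with a median of -1.38 (adjusted p = 7.65e-24; adjusted p = 0.262 with an estimated correlation). Its members with the smallest p were Ankrd1, Tpm2 (-2.36), Ccn1 (-1.47) and Lmod1 (-2.44). Among ATF4 targets, the genes of the amino acid stress response, 29 of 37 were lower, 1 higher and 7 not past, against 31 and 2 adjusted over the list alone. Their median was -0.51 (adjusted p = 5.64e-16; adjusted p = 0.0581 with an estimated correlation). Chac1 (-2.20), Mthfd2 (-1.84), Asns (-0.88) and Slc1a4 (-1.21) led them. Cholesterol biosynthesis genes were lower in 18 of 19 cases, and in 18 adjusted over the list alone, with Hsd17b7 at -1.54 and Lss at -1.63. The median was -0.82 (adjusted p = 5.75e-15; adjusted p = 0.325 with an estimated correlation). G2/M and mitosis genes, 60 in number, were lower in 29 cases, higher in 2 and not past in 29, against 37 and 2 adjusted over the list alone, with Prc1 at -0.83 and Foxm1 at -0.70. Their median was -0.31 (adjusted p = 9.37e-09; adjusted p = 0.573 with an estimated correlation). The fibroblast and extracellular matrix list had 23 lower, 3 higher and 10 not past, the same numbers adjusted over the list alone (23 and 3), with Thy1 and Cd44 lower (-1.03 and -1.02) and Dcn higher (1.68). The median was -0.40 (adjusted p = 6.6e-06; adjusted p = 0.573 with an estimated correlation). Mesenchymal transcription and TGF-beta signalling genes had 10 lower, 4 higher and 4 not past, against 11 and 5 adjusted over the list alone, among them Snai1 (-1.30) and Ltbp2 (-2.22). Their median was -0.63 (adjusted p = 0.00169; adjusted p = 0.553 with an estimated correlation).

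Interferon response genes rose in WT cells: 23 of 44 were higher, 0 lower and 21 not past, and 33 were higher adjusted over the list alone, with Oasl2 at 2.76 ± 0.40 and Ifit1 at 2.84 ± 0.49. The median was 1.19 (adjusted p = 4e-10; adjusted p = 0.573 with an estimated correlation). The interferon response median was 0.58 without WT day 4 array 1 (adjusted p = 3.21e-07). The mean of this list, each gene centred over the 12 arrays, was 0.92 in WT day 4 array 1 against -0.44 and -0.91 in WT day 4 arrays 2 and 3, and it lay between -1.36 and -1.32 in the WT day 0 arrays. Macrophage and blood markers did not shift (2 of 24 higher, 3 lower, and the same 2 and 3 adjusted over the list alone; median -0.03, mean 0.03, adjusted p = 0.946). Endoplasmic reticulum folding genes had 13 of 24 lower, 0 higher and 11 not past, against 17 lower and 2 higher adjusted over the list alone, with Herpud1 at -0.45. Their median was -0.28 (adjusted p = 8.65e-05; adjusted p = 0.516 with an estimated correlation). Calcium entry and microtubule genes had 15 of 26 lower, 3 higher and 8 not past, unchanged at 15 and 3 adjusted over the list alone, with Tubb3 at -2.23 and Stmn2 at 2.54. The median was -0.30 (adjusted p = 0.00128; adjusted p = 0.262 with an estimated correlation). Peroxisome genes had 11 of 24 higher, 2 lower and 11 not past, against 14 and 2 adjusted over the list alone, with Pex10 at 0.60. Their median was 0.22 (adjusted p = 0.00407; adjusted p = 0.262 with an estimated correlation). Immediate early and ERK feedback genes had 10 of 27 lower, 3 higher and 14 not past, against 13 and 5 adjusted over the list alone, with Dusp5 at -1.27 and Etv4 at -1.23. The median was -0.28 (adjusted p = 0.00711; adjusted p = 0.363 with an estimated correlation). It was -0.14 without WT day 4 array 2 (adjusted p = 0.0191). Keratinocyte markers had 8 of 17 higher, 1 lower and 8 not past, unchanged adjusted over the list alone (8 and 1), with Krt14 at 1.51 and Sprr1a at 1.54. Their median was 0.13 (adjusted p = 0.0075; adjusted p = 0.262 with an estimated correlation), a call lost when genes under the 25th percentile of level were left out (adjusted p = 0.0638).

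Skeletal muscle markers barely passed in WT cells, with 5 of 22 lower, 0 higher and 17 not past, and 6 lower adjusted over the list alone. The median was -0.10 (adjusted p = 0.0468; adjusted p = 0.363 with an estimated correlation). Acta1 (-2.12) and Des (-1.74) led them, and the call was lost without WT day 0 array 1 (adjusted p = 0.0533) or array 3 (0.0532) or without WT day 4 array 3 (0.174), and also without genes under the 25th percentile (0.0838) or with the average of probe sets (0.0577). DNA replication genes had 16 of 49 lower, 3 higher and 30 not past, against 17 and 3 adjusted over the list alone, with Clspn at -0.50 and E2f2 at 0.73. Their median was -0.11 (adjusted p = 0.0489; adjusted p = 0.711 with an estimated correlation). That call was lost without any 1 of 5 arrays: WT day 0 array 3 (adjusted p = 0.0832), WT day 4 array 1 (median -0.02, 0.435) or 2 (0.0879), and KO day 4 array 1 (0.0524) or 2 (0.0501), whereas without WT day 4 array 3 the DNA replication median was -0.22 (0.000527). It was also lost without genes under the 25th percentile (0.0838), with quantile normalization (0.0598), the average of probe sets (0.0662) or array weights (0.18), in a fit to the 2 groups alone (0.0505), and without WT day 4 array 1 and KO day 4 array 2 together, an omission chosen after the data were seen (0.466). Without WT day 4 array 1 the hypoxia response list was lower (median -0.45, adjusted p = 0.00042), where with it the list did not pass (3 of 19 higher; median 0.04, adjusted p = 0.701). Glycolysis genes were likewise lower without it (median -0.23, adjusted p = 0.0201) and higher without WT day 4 array 3 (0.12, adjusted p = 0.0395), with 4 of 20 higher in the full data (median 0.00, adjusted p = 0.332). Secreted inflammatory factors were lower without array 1 (median -0.21, adjusted p = 0.0229), higher without array 3 (0.64, adjusted p = 0.00261), and in the full data 5 were higher and 4 lower of 36 (median 0.19, adjusted p = 0.289). Epithelial genes, 8 higher and 3 lower of 38, had a median of -0.00 with a mean of 0.09 and a test pointing up (adjusted p = 0.5). For the pluripotency list the median was -0.01 and the mean 0.02, with 6 higher and 4 lower of 38 (adjusted p = 0.728), and for mitochondrial dynamics they were -0.00 and 0.04 (4 higher and 2 lower of 30, adjusted p = 0.683). Endothelial markers had a median of -0.09, a mean of 0.02 and a test pointing down (4 higher, 4 lower of 19, adjusted p = 0.5). No shift passed for p53 targets (41 genes, adjusted p = 0.234), neural and Schwann cell markers (23, 0.26), citric acid cycle genes (19, 0.0647), the transduced factors as a list (4, 0.382) or the X- and Y-linked sex markers (4, 0.0555). The citric acid cycle list passed without WT day 4 array 1 (adjusted p = 0.0384) or with quantile normalization (0.0322), and the sex markers passed without WT day 0 array 2 (0.0379), WT day 4 array 1 (0.0372) or KO day 4 array 2 (0.0489), and with quantile normalization (0.0498) or array weights (0.0362).

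In KO cells the same step from day 0 to day 4 was compared, again without separating reprogramming from transduction and time in culture. Ceacam1 rose 33-fold (5.05 ± 0.23, SE, n = 3 per group, adjusted p = 3.4e-08) and Sostdc1, a secreted antagonist of BMP and Wnt signalling, 26.9-fold (4.75 ± 0.23, adjusted p = 4.53e-08). Oas2, an interferon-induced gene, rose 20-fold (4.32 ± 0.52, adjusted p = 4.65e-05). Further large rises were those of Crym (4.49 ± 0.29), Lbp (4.45 ± 0.37), Ces1f (4.28 ± 0.34), Akr1c18 (4.16 ± 0.09), Aldh3a1 (4.15 ± 0.37), Tek (4.12 ± 0.17) and Scara5 (3.61 ± 0.28). Cnn1 fell by 3.13 ± 0.43 on the log2 scale (adjusted p = 0.00012), the lipase gene Lipg by 2.91 ± 0.18 (adjusted p = 4.12e-07), and the remaining largest falls, in Gpr149, Ptprn, Lrrc15, Tubb3, Prnd, Ppbp, Tnmd and Actg2, lay between -2.78 and -2.41. In all, 6828 genes passed, 3071 higher and 3757 lower, of which 529 rose and 305 fell at least 2-fold. Across genes, the day 4 changes of KO and WT cells had a Pearson correlation of 0.737 (Spearman 0.598), and genes are not independent replicates. Both changes passed in the same direction for 1648 genes higher and 1798 lower, where independent calls would give 342 and 441, and they passed in opposite directions for 72.

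**Figure D2:**
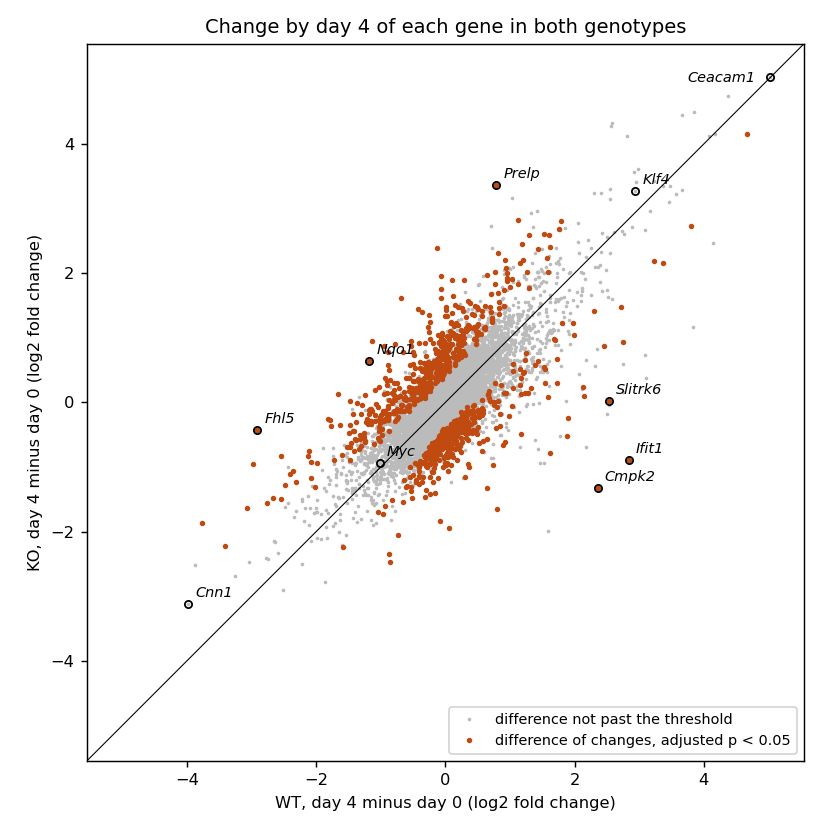
Log2 change from day 0 to day 4 of each of 22180 genes in WT cells (x axis) and in KO cells (y axis), n = 3 arrays per group, with orange points for the 877 genes whose changes differed past the threshold.

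Among the lists, 14 shifted in KO cells, 2 up and 12 down, and 0 held with an estimated correlation in camera (4 had an unadjusted p under 0.05). G2/M and mitosis genes were lower in 40 of 60 cases, higher in 1 and not past in 19, against 48 and 1 adjusted over the list alone, with Prc1 at -0.95 and Cdc25c at -1.20. The median was -0.53 (adjusted p = 1.93e-14; adjusted p = 0.516 with an estimated correlation). All 23 actin cytoskeleton and smooth muscle genes were lower, also adjusted over the list alone (23), among them Ankrd1 at -2.23 and Flna at -1.26. Their median was -1.06 (adjusted p = 1.82e-13; adjusted p = 0.363 with an estimated correlation). Cholesterol biosynthesis genes had 17 of 19 lower, and 18 adjusted over the list alone, with Nsdhl at -1.33 and Lss at -1.82. The median was -0.92 (adjusted p = 4.13e-13; adjusted p = 0.326 with an estimated correlation). ATF4 targets had 25 of 37 lower, 2 higher and 10 not past, against 26 and 2 adjusted over the list alone, with Mthfd2 at -2.10 and Atf5 at -1.43. Their median was -0.56 (adjusted p = 4e-10; adjusted p = 0.132 with an estimated correlation). For DNA replication, 33 of 49 were lower, 1 higher and 15 not past, against 38 and 2 adjusted over the list alone, with Mcm5 at -1.08 and E2f8 at -1.04. The median was -0.37 (adjusted p = 1.27e-09; adjusted p = 0.512 with an estimated correlation). Ribosome biogenesis and MYC target genes had 23 of 46 lower, 5 higher and 18 not past, against 27 and 5 adjusted over the list alone, with Nme1 at -1.23 and Odc1 at -1.09. Their median was -0.28 (adjusted p = 7.9e-06; adjusted p = 0.573 with an estimated correlation). In WT cells that list did not pass (10 higher, 8 lower; median 0.10, adjusted p = 0.234).

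Endoplasmic reticulum folding genes had 15 of 24 lower and 2 higher in KO cells, unchanged adjusted over the list alone (15 and 2), with Hyou1 at -0.85 and Hspa5 at -0.60. The median was -0.44 (adjusted p = 1.59e-05; adjusted p = 0.5 with an estimated correlation). Calcium entry and microtubule genes had 14 of 26 lower and 3 higher, against 15 and 5 adjusted over the list alone, with Tubb6 at -1.80 and Stmn2 at 3.31. Their median was -0.34 (adjusted p = 0.00142; adjusted p = 0.262 with an estimated correlation). Hypoxia response genes were higher in 5 of 19 cases and lower in 0, also adjusted over the list alone (5), with Epas1 at 1.97 ± 0.21 and Mxi1 at 1.05 ± 0.16. The median was 0.62 (adjusted p = 0.00287; adjusted p = 0.637 with an estimated correlation). Glycolysis genes were higher in 7 of 20 cases and lower in 0, also 7 adjusted over the list alone, with the glucose transporter gene Slc2a3 at 2.32 ± 0.17 and Aldoc at 2.31 ± 0.24. Their median was 0.15 (adjusted p = 0.0244; adjusted p = 0.694 with an estimated correlation), a call lost when list members were matched through any synonym (adjusted p = 0.0541). Macrophage and blood markers did not shift (2 of 24 higher, 0 lower; median 0.06, adjusted p = 0.556). Mesenchymal genes had 10 of 18 lower and 3 higher, against 11 and 3 adjusted over the list alone, with Cdh2 at -1.52. The median was -0.61 (adjusted p = 0.00436; adjusted p = 0.573 with an estimated correlation). For the fibroblast and extracellular matrix list, 15 of 36 were lower and 5 higher, also adjusted over the list alone, with Twist2 at -1.73. Their median was -0.18 (adjusted p = 0.0189; adjusted p = 0.694 with an estimated correlation), a call lost without KO day 4 array 1 (adjusted p = 0.0592) or 3 (0.0865), without genes under the 25th percentile (0.0638) or with quantile normalization (0.0585), while without KO day 4 array 2 the median was -0.28 (0.000344). HOX genes had 10 of 36 lower and 1 higher, also adjusted over the list alone, with Hoxb9 at -1.16. The median was -0.11 (adjusted p = 0.0199; adjusted p = 0.584 with an estimated correlation), a call lost without KO day 4 array 1 (adjusted p = 0.0598) or without genes under the 25th percentile (0.0642). Oxidative phosphorylation genes had 23 of 69 lower and 7 higher, against 26 and 10 adjusted over the list alone, with Uqcrq at -0.94 and Ndufa6 at 0.86. Their median was -0.19 (adjusted p = 0.0468; adjusted p = 0.586 with an estimated correlation). That call was lost with quantile normalization (median -0.14, adjusted p = 0.282), without genes under the 25th percentile (0.117), and without WT day 4 array 1 and KO day 4 array 2 together (0.0588). It was also lost without any 1 of 6 arrays, with adjusted p up to 0.0804: WT day 4 arrays 2 and 3, KO day 0 arrays 2 and 3, and KO day 4 arrays 2 and 3. Interferon response genes did not shift in KO cells (3 higher, 6 lower of 44; median -0.28, adjusted p = 0.593), nor did secreted inflammatory factors (3 higher, 6 lower of 36; adjusted p = 0.461). The interferon response mean of KO day 4 array 2 was 1.20 against 0.37 and 0.49 in the other KO day 4 arrays; without it the median was -0.48 (adjusted p = 0.0982), and without WT day 4 array 1 as well the list passed (-0.48, adjusted p = 0.00415). Without KO day 4 array 1 or 3 the interferon response median was -0.11 or -0.17. Endothelial markers had a median of -0.04, a mean of 0.19 and a test pointing up (adjusted p = 0.57).

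The KO and WT cells at day 0 were compared to describe how the genotypes differed before reprogramming. Interferon-induced and inflammatory genes were higher in KO cells: Ifit1, which encodes an antiviral RNA-binding protein, by 4.96 ± 0.49 (SE, n = 3 per group, 31.1-fold, adjusted p = 7.38e-05), Cxcl10, a chemokine gene, by 4.60 ± 0.76 (adjusted p = 0.00288), Mmp3, a matrix metalloproteinase gene, by 4.66 ± 0.87 (adjusted p = 0.00626), and Saa3 by 5.25 ± 1.06 (38-fold, adjusted p = 0.0101, and 0.057 with a trended robust prior). Steap4, Cmpk2, Usp18, Mmp10, Ifi205 and Iigp1 completed the largest rises, between 3.52 and 4.27. Car3, a carbonic anhydrase gene, was lower by 10.7-fold (-3.42 ± 0.23, adjusted p = 4.81e-06), and Eln, which encodes elastin, by 9.29-fold (-3.22 ± 0.33, adjusted p = 9.06e-05). C1qb, a complement gene of macrophages, was lower by 8.7-fold (-3.12 ± 0.18, adjusted p = 2.69e-06), and Ms4a7, Fhl5, Gjb2, Lilrb4a, Fcer1g, Fcrls and Prelp lay between -2.94 and -2.26. In all, 1242 genes passed, 549 higher and 693 lower, of which 145 and 128 differed at least 2-fold. The count fell to between 769 and 826 without any 1 of the 6 day 0 arrays and rose to 1936 without WT day 4 array 1, to 2562 with array weights and to 2453 in a fit to these 2 groups alone. Of the sex markers, Xist was higher in KO cells at day 0 (0.42 ± 0.09, adjusted p = 0.0158) and Uty lower (-0.34 ± 0.09, adjusted p = 0.0435), while Kdm5d (-0.28, adjusted p = 0.159) and Eif2s3y (-0.17, adjusted p = 0.443) did not pass and Ddx3y was not measured. The Xist call was lost in 5 of the 12 single omissions (WT day 0 arrays 1 and 3 and each KO day 0 array, adjusted p up to 0.0845). The Uty call was lost in 7 (each day 0 array and KO day 4 array 3, up to 0.164), and Kdm5d passed without WT day 4 array 1 (0.0486) and with array weights (0.0409).

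At day 0, 15 lists shifted between the genotypes, 6 higher in KO cells and 9 lower, and 0 held with an estimated correlation in camera (3 had an unadjusted p under 0.05). Interferon response genes were higher in 33 of 44 cases and lower in 0, with 11 not past and 38 higher adjusted over the list alone, including Oasl2 (3.49 ± 0.40) and Rtp4 (3.34 ± 0.39). The median was 2.24 (adjusted p = 3.09e-42; adjusted p = 0.326 with an estimated correlation). Secreted inflammatory factors were higher in 14 of 36 cases and lower in 0, and 23 were higher adjusted over the list alone, including Mmp10 (3.58 ± 0.21), Il6 (3.11 ± 0.51) and Cxcl3 (1.30 ± 0.20). Their median was 0.98 (adjusted p = 1.58e-12; adjusted p = 0.516 with an estimated correlation). Beside these rises, macrophage and blood markers were lower in 20 of 24 cases, higher in 0 and not past in 4, with 21 lower adjusted over the list alone. The median was -1.07 (adjusted p = 2e-28; adjusted p = 0.0561 with an estimated correlation). Laptm5 (-1.64 ± 0.11), Cd68 (-1.27 ± 0.09) and Fcer1g (-2.30 ± 0.18) were among them, and the macrophage list means lay between 0.53 and 0.59 in the WT day 0 arrays and between -0.66 and -0.57 in the KO day 0 arrays. Hypoxia response genes had a median of 0.36 (adjusted p = 0.000618; adjusted p = 0.6 with an estimated correlation), with 0 of 19 past the threshold in limma, also 0 adjusted over the list alone; of its smallest p-values, Hif1a (0.55 ± 0.15, adjusted p = 0.0545) passed without WT day 4 array 1 (0.00258) or 3 (0.00778), and Kdm3a (0.36 ± 0.12, adjusted p = 0.121) passed without array 1 (0.0151). Both passed with array weights (0.0021 and 0.0108) and in a fit to the 2 groups alone (0.000458 and 0.0115), and Hif1a also without genes under the 25th percentile (0.0457) or with the average of probe sets (0.0204). Glycolysis genes had a median of 0.27 (adjusted p = 0.00109; adjusted p = 0.611 with an estimated correlation), and Slc16a1, a lactate transporter gene, was the single member higher (1.33 ± 0.14, adjusted p = 9.82e-05), also adjusted over the list alone (1).

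The remaining shifts at day 0 were smaller than 0.30 in median. G2/M and mitosis genes had 3 of 60 lower, also adjusted over the list alone (median -0.21, adjusted p = 6.92e-11; adjusted p = 0.553 with an estimated correlation): Cdca3 (-0.37), Prc1 (-0.34, lost in 5 of the 12 single omissions) and Cdc20 (-0.38, lost in 6). DNA replication genes had a median of -0.15 (adjusted p = 2.39e-06; adjusted p = 0.569 with an estimated correlation), with Prim2 alone lower (-0.37, lost in 5 omissions) and 0 adjusted over the list alone. Actin and smooth muscle genes had Srf (-0.40), Tpm2 (-0.50) and Zyx (-0.43) lower, 3 of 23 and 4 adjusted over the list alone (median -0.29, adjusted p = 9.16e-06; adjusted p = 0.569 with an estimated correlation), and these genes lost their calls in 2, 6 and 8 omissions. HOX genes had 6 of 36 higher and 0 lower, 7 adjusted over the list alone, with Hoxa5 at 0.52 and Hoxd10 at 0.52. Their median was 0.13 (adjusted p = 7.25e-05; adjusted p = 0.5 with an estimated correlation). ATF4 targets had 5 of 37 lower and 2 higher, against 10 and 3 adjusted over the list alone, with Slc7a1 at -0.52 and Chac1 at -0.73. The median was -0.15 (adjusted p = 0.000192; adjusted p = 0.326 with an estimated correlation). For cholesterol biosynthesis, Dhcr7 (-0.54) and Nsdhl (-0.39, lost in 10 omissions and with median centring, adjusted p = 0.057) were the 2 of 19 lower, also adjusted over the list alone. Their median was -0.18 (adjusted p = 0.000817; adjusted p = 0.573 with an estimated correlation). NRF2 targets and oxidative stress genes had 3 of 35 higher and 1 lower, against 6 and 2 adjusted over the list alone, with Gsta4 at -1.62. The median of these oxidative stress and NRF2 targets was 0.11 (adjusted p = 0.00335; adjusted p = 0.573 with an estimated correlation), and 0.16 without KO day 0 array 1. In the homologous recombination and repair list H2ax alone was lower (-0.49, lost in 4 omissions), also adjusted over the list alone. Their median was -0.11 (adjusted p = 0.00548; adjusted p = 0.611 with an estimated correlation). Ribosome biogenesis genes had a median of -0.08 (adjusted p = 0.00548; adjusted p = 0.637 with an estimated correlation) with 0 of 46 past the threshold in limma, also 0 adjusted over the list alone; Bysl (-0.35) had the smallest p (adjusted p = 0.0679) and passed without WT day 4 array 1 (0.0434) or KO day 0 array 1 (0.0419) or with array weights (0.0244). Cartilage, bone and fat markers had 4 of 20 lower and 1 higher, against 5 and 1 adjusted over the list alone, with Dlx5 at -1.51 and Pparg at -0.62. The median was -0.15 (adjusted p = 0.016; adjusted p = 0.45 with an estimated correlation). Mitochondrial dynamics genes had 0 of 30 past the threshold and a median of -0.05 with a mean of 0.00 (adjusted p = 0.387). The median of skeletal muscle markers was -0.01 with a test pointing up (adjusted p = 0.833).

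**Figure D3:**
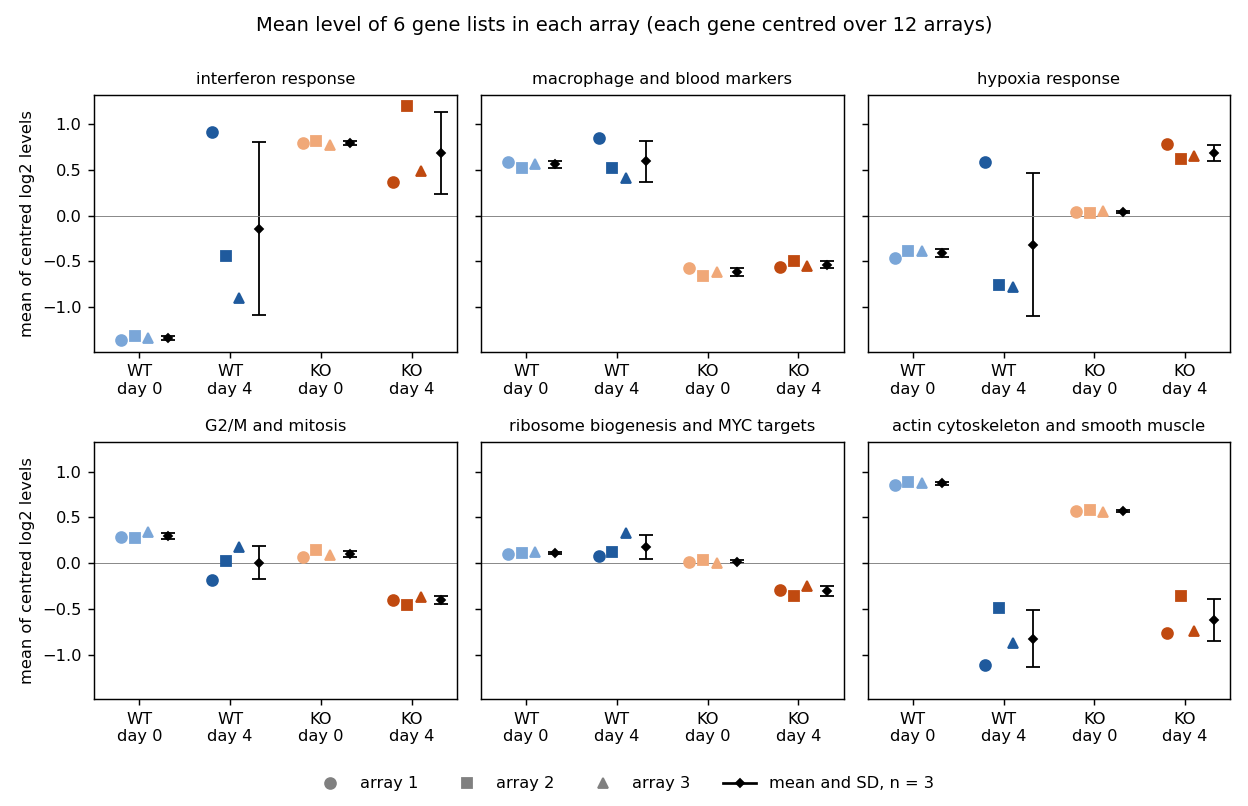
Mean of each gene list per array (y axis, log2, each gene centred over the 12 arrays) by group (x axis), with points for arrays and diamonds with bars for the group mean and SD (n = 3). Macrophage marker means lay between 0.42 and 0.85 in the 6 WT arrays and between -0.66 and -0.49 in the 6 KO arrays, and WT day 4 array 1 lay at 0.59 for hypoxia response against -0.76 and -0.78 for the other two.

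The KO and WT cells at day 4 were compared to describe how the genotypes differed during reprogramming. Macrophage genes were lower in KO cells again, with C1qb at -3.23 ± 0.18 (SE, n = 3 per group, adjusted p = 8.97e-07), Tyrobp, an immune receptor adaptor gene, at -1.95 ± 0.16 (adjusted p = 1.88e-05) and Adgre1, which encodes the macrophage surface protein F4/80, at -1.99 ± 0.45 (adjusted p = 0.00817). Car3 was lower by 10.7-fold (-3.42 ± 0.23, adjusted p = 4.06e-06), and Ms4a7, Fcer1g, Chrdl1, Folr2, Reg1 and Slitrk6 lay between -2.41 and -1.99. Higher in KO cells were Oas2 (2.56 ± 0.52, adjusted p = 0.00439), the transglutaminase gene Tgm1 (2.49 ± 0.51, adjusted p = 0.00439), Elobl (2.46 ± 0.13, adjusted p = 6.4e-07), Mmp13, Prg4, Kng2, Mcpt8 and Adssl1. Ndufa4l2, a hypoxia-induced gene, was higher by 2.46 ± 0.65 (adjusted p = 0.0181) and Bnip3, a mitophagy receptor gene, by 2.00 ± 0.50 (adjusted p = 0.0132). Without WT day 4 array 2 or 3 these calls were lost (adjusted p = 0.0768 and 0.0837 for Ndufa4l2, 0.0574 and 0.0627 for Bnip3), and without KO day 4 array 2 that of Ndufa4l2 as well (0.0516), which a trended robust prior also ended (0.0632). Myc was higher in KO cells (0.36 ± 0.08, adjusted p = 0.00949), while Klf4 (0.11, adjusted p = 0.409), Pou5f1 (0.10, adjusted p = 0.491) and Sox2 (0.02, adjusted p = 0.935) did not differ past the threshold. In all, 4596 genes passed, 1850 higher and 2746 lower, of which 199 and 131 differed at least 2-fold, and without WT day 4 array 3 the count fell to 2946. A fit to these 2 groups alone gave 1923, and it ended the calls of Adgre1 (adjusted p = 0.0647), Chrdl1 (0.0579), Mmp13 (0.0768), Ndufa4l2 (0.0994), Bnip3 (0.0846), Myc (0.0646) and Uty (0.0731), while Adgre1 was -1.22 without WT day 4 array 1. Across genes the genotype differences of day 0 and day 4 had a Pearson correlation of 0.495 (Spearman 0.369). On both days 259 genes were higher and 287 lower, where independent calls would give 45.8 and 85.8, and 46 passed in opposite directions. Xist was higher at day 4 (0.46 ± 0.09, adjusted p = 0.00449), and Kdm5d (-0.56, adjusted p = 0.00229) and Uty (-0.38, adjusted p = 0.0102) were lower, while Eif2s3y did not pass (-0.29, adjusted p = 0.0609) except without KO day 4 array 3 (0.0356), without genes under the 25th percentile (0.0477), with median centring (0.0486) or with a trended robust prior (0.0447).

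At day 4, 16 lists shifted between the genotypes, 7 higher in KO cells and 9 lower, and 0 held with an estimated correlation in camera (6 had an unadjusted p under 0.05). Ribosome biogenesis and MYC target genes were lower in 34 of 46 cases, higher in 1 and not past in 11, against 39 and 1 adjusted over the list alone, with Bop1 at -0.80 ± 0.07 and Cad at -0.95 ± 0.09. Their median was -0.48 (adjusted p = 2.92e-19; adjusted p = 0.326 with an estimated correlation). G2/M and mitosis genes were lower in 39 of 60 cases and higher in 0, with 50 lower adjusted over the list alone, including Cdc20 at -0.94 ± 0.09 and Plk1 at -0.79 ± 0.10. The median was -0.43 (adjusted p = 1.46e-17; adjusted p = 0.457 with an estimated correlation). For DNA replication, 34 of 49 were lower and 0 higher, with 36 lower adjusted over the list alone, including Mcm5 at -1.20 ± 0.14. Their median was -0.46 (adjusted p = 1.94e-16; adjusted p = 0.358 with an estimated correlation). Oxidative phosphorylation genes were lower in 32 of 69 cases and higher in 2, against 34 and 2 adjusted over the list alone, with Ndufa2 at -0.77 ± 0.08 and Cyc1 at -0.58 ± 0.08. The median was -0.21 (adjusted p = 1.54e-07; adjusted p = 0.326 with an estimated correlation). Mitochondrial ribosome genes were lower in 27 of 65 cases and higher in 1, against 28 and 2 adjusted over the list alone, with Mrpl49 at -0.64 ± 0.09. Their median was -0.19 (adjusted p = 4.27e-07; adjusted p = 0.363 with an estimated correlation). Homologous recombination and repair genes had 17 of 38 lower and 1 higher, against 19 and 1 adjusted over the list alone, with Chek1 at -0.74. The median was -0.24 (adjusted p = 0.000192; adjusted p = 0.573 with an estimated correlation). Cholesterol biosynthesis genes had 7 of 19 lower, also adjusted over the list alone, with Nsdhl at -0.64. Their median was -0.24 (adjusted p = 0.0012; adjusted p = 0.583 with an estimated correlation), and -0.14 without WT day 4 array 2 (adjusted p = 0.0361). Endoplasmic reticulum folding genes had 7 of 24 lower and 1 higher, also adjusted over the list alone, with Herpud1 at -0.69. The median was -0.14 (adjusted p = 0.00958; adjusted p = 0.584 with an estimated correlation), a call lost without WT day 4 array 1 (adjusted p = 0.0653).

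Higher in KO cells at day 4 were 14 of 19 hypoxia response genes, with 0 lower and 17 higher adjusted over the list alone, among them Vegfa at 1.17 ± 0.24 and Slc2a1, a glucose transporter gene, at 1.37 ± 0.31. Their median was 0.83 (adjusted p = 2.4e-08; adjusted p = 0.538 with an estimated correlation). The hypoxia list mean of WT day 4 array 1 (0.59) lay beside the KO day 4 arrays (0.62 to 0.78), while those of WT day 4 arrays 2 and 3 were -0.76 and -0.78. Without array 1 the hypoxia response median was 1.28 (adjusted p = 3.17e-21). Glycolysis genes were higher in 8 of 20 cases and lower in 0, and 12 adjusted over the list alone, with Slc2a3 at 0.96 ± 0.17 and Pfkp at 1.28 ± 0.27. The median was 0.49 (adjusted p = 3.55e-06; adjusted p = 0.573 with an estimated correlation). Their means were 0.45 in WT day 4 array 1, -0.47 and -0.50 in arrays 2 and 3, and 0.43 to 0.49 in the KO day 4 arrays, and without array 1 the glycolysis median was 0.88 (adjusted p = 9.57e-17). Interferon response genes were higher in 16 of 44 cases and lower in 0, and 22 adjusted over the list alone, with Oas3 at 1.31 ± 0.19 and Gbp3 at 1.85 ± 0.40. Their median was 0.77 (adjusted p = 1.46e-07; adjusted p = 0.586 with an estimated correlation). Their means were 0.92 in WT day 4 array 1 and 0.37 to 1.20 in the KO day 4 arrays. The interferon response median was 1.36 without WT day 4 array 1 (adjusted p = 5.64e-21), 0.44 without array 3 (0.000359) and 0.48 without KO day 4 array 2 (0.000452). Secreted inflammatory factors were higher in 6 of 36 cases and lower in 2, against 8 and 2 adjusted over the list alone, with Mmp10 at 1.82 ± 0.21 and Ptgs2 at 1.80 ± 0.31. The median was 0.53 (adjusted p = 0.00264; adjusted p = 0.682 with an estimated correlation), a call lost without WT day 4 array 3 (0.19, adjusted p = 0.223). Without WT day 4 array 1, whose mean of 1.00 lay above the KO day 4 arrays (0.26 to 0.69), the median of secreted inflammatory factors was 1.31 (adjusted p = 4.86e-16). Macrophage and blood markers were lower in 19 of 24 cases and higher in 0, with 20 lower adjusted over the list alone, among them Cd68 at -1.63 ± 0.09. Their median was -0.89 (adjusted p = 2.07e-15; adjusted p = 0.132 with an estimated correlation). Immediate early and ERK feedback genes were higher in 11 of 27 cases and lower in 1, against 14 and 1 adjusted over the list alone, with Dusp6 at 0.94 ± 0.13. The median was 0.22 (adjusted p = 7.28e-05; adjusted p = 0.262 with an estimated correlation), and 0.34 without WT day 4 array 1 (adjusted p = 1.52e-05). NRF2 targets and oxidative stress genes were higher in 13 of 35 cases and lower in 2, against 14 and 3 adjusted over the list alone, with Nqo1 at 1.89 ± 0.15. The median of these oxidative stress and NRF2 targets was 0.32 (adjusted p = 0.00157; adjusted p = 0.553 with an estimated correlation), and 0.18 without WT day 4 array 3 (adjusted p = 0.00639). Actin and smooth muscle genes were higher in 6 of 23 cases and lower in 2, against 7 and 2 adjusted over the list alone, with Ccn1 at 1.01 ± 0.09. The median was 0.26 (adjusted p = 0.0377; adjusted p = 0.694 with an estimated correlation). That call was lost without WT day 4 array 1 (median 0.05, adjusted p = 0.473) or array 3 (0.18, 0.0605) or KO day 4 array 2 (0.08, 0.343), or with array weights (0.09, 0.374), and without WT day 4 array 2 the median of actin cytoskeleton and smooth muscle genes was 0.40 (3.16e-05). A fit to the 2 groups alone ended the calls of Slc2a1 (adjusted p = 0.0633), Pfkp (0.0549) and Gbp3 (0.0551). Peroxisome genes had a median of -0.04, a mean of 0.04 and a test pointing up (6 higher, 3 lower of 24, adjusted p = 0.644). Mitochondrial dynamics genes had 8 of 30 lower and 3 higher, and the list did not pass (median -0.07, adjusted p = 0.102).

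The difference between the day 4 changes of KO and WT cells asks whether the change to day 4 differed between the genotypes. Prelp, which encodes a matrix proteoglycan, had a difference of 2.58 ± 0.17, KO minus WT (SE, n = 3 per group, adjusted p = 5.14e-05), and Fhl5 of 2.49 ± 0.22 (adjusted p = 0.000224). Nppb, a natriuretic peptide gene, had 2.52 ± 0.35 (adjusted p = 0.00276) and Nqo1, an NRF2 target, 1.83 ± 0.21 (adjusted p = 0.00103). Lgr5, Lurap1l, Map3k7cl, Elobl, Gjb2 and Fabp4 completed the largest positive differences, between 1.87 and 2.31. Ifit1 had a difference of -3.74 ± 0.69 (adjusted p = 0.012) and Cmpk2 of -3.69 ± 0.56 (adjusted p = 0.00456), and both genes were higher in KO cells at day 0. Slitrk6, Oasl1, Irgm2, Mx2, Gbp7, Reg1, Cbr2 and Clstn2 lay between -2.52 and -1.98. The calls of Fabp4, Oasl1, Irgm2, Mx2 and Gbp7 were lost in 11, 8, 8, 9 and 8 of the 12 single omissions (adjusted p up to 0.109, 0.0759, 0.0633, 0.111 and 0.0826), and with a trended robust prior (0.0984, 0.0718, 0.0658, 0.103 and 0.0812). Gdap1 (0.23, adjusted p = 0.505), Sox2 (-0.28, adjusted p = 0.415), Klf4 (0.34, adjusted p = 0.146) and Myc (0.08, adjusted p = 0.795) did not pass. In all, 877 genes passed, 476 positive and 401 negative, of which 123 and 56 differed at least 2-fold. The negative genes outnumbered the positive ones with median centring (511 and 451), a trended robust prior (668 and 619) or array weights (1024 and 828), and without WT day 4 array 1 (1178 and 962). The count rose to 2140 without WT day 4 array 1 and to 1852 with array weights. With all probe sets 503 passed, and the count of genes fell to between 395 and 576 without any 1 of the 6 day 0 arrays, WT day 4 array 3, or KO day 4 array 1 or 3.

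The lists gave 11 shifts in this difference, 4 positive and 7 negative, and 0 with an estimated correlation in camera (2 had an unadjusted p under 0.05). Ribosome biogenesis and MYC target genes had 9 of 46 negative and 0 positive, with 25 negative adjusted over the list alone, including Bop1 at -0.71 ± 0.10 and Cad at -0.90 ± 0.13. Their median was -0.39 (adjusted p = 1.58e-16; adjusted p = 0.358 with an estimated correlation). Interferon response genes had 6 of 44 negative and 1 positive, against 28 and 1 adjusted over the list alone, with Ifit2 at -1.22 ± 0.23. The median was -1.25 (adjusted p = 7.27e-12; adjusted p = 0.573 with an estimated correlation). It was -0.77 (adjusted p = 1e-07) without WT day 4 array 1, whose interferon response mean stood apart (0.92). DNA replication genes had 8 of 49 negative and 0 positive, with 15 negative adjusted over the list alone, including Pola2 at -0.56 ± 0.11. Their median was -0.27 (adjusted p = 7.82e-09; adjusted p = 0.516 with an estimated correlation). G2/M and mitosis genes had 4 of 60 negative and 0 positive, with 12 negative adjusted over the list alone (median -0.21, adjusted p = 1.75e-06; adjusted p = 0.584 with an estimated correlation), and the calls of Ncapd2, Cdc20, Cdc25c and Kif2c were each lost in at least 9 of the 12 single omissions. The G2/M and mitosis median was -0.13 without WT day 4 array 3 (adjusted p = 0.0013). Oxidative phosphorylation genes had 4 of 69 negative and 0 positive, with 7 negative adjusted over the list alone, including Uqcrq at -0.58 ± 0.11. The median was -0.16 (adjusted p = 2.35e-05; adjusted p = 0.428 with an estimated correlation). Mitochondrial ribosome genes had a median of -0.18 (adjusted p = 2.39e-05; adjusted p = 0.45 with an estimated correlation), with 0 of 65 past the threshold in limma, also 0 adjusted over the list alone. Mrpl11 (-0.62, adjusted p = 0.0657) and Mrpl49 (-0.42, adjusted p = 0.0739) had the smallest p-values there, and both passed without WT day 4 array 1 (0.0391 and 0.0478), with a trended robust prior (0.0492 and 0.0436) and with array weights (0.0298 and 0.0491).

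Actin and smooth muscle genes fell less in KO than in WT cells, with 5 of 23 positive and 0 negative, 7 positive adjusted over the list alone, and Ccn1 at 1.12 ± 0.13 and Tpm2 at 1.29 ± 0.17. The median of these actin cytoskeleton and smooth muscle genes was 0.45 (adjusted p = 1.88e-07; adjusted p = 0.516 with an estimated correlation), and 0.25 without WT day 4 array 1 (adjusted p = 0.000147). Immediate early and ERK feedback genes had 3 of 27 positive and 1 negative, against 11 and 1 adjusted over the list alone, with Dusp5 at 0.73 ± 0.12 and Spry1 at 1.26 ± 0.24. The median was 0.19 (adjusted p = 0.000496; adjusted p = 0.262 with an estimated correlation), and 0.38 without WT day 4 array 1 (adjusted p = 1.45e-05). Hypoxia response genes had a median of 0.54 (adjusted p = 0.00172; adjusted p = 0.629 with an estimated correlation), with 0 of 19 past the threshold in limma, also 0 adjusted over the list alone, and the call was lost without WT day 4 array 2 (adjusted p = 0.0655) or 3 (0.34, 0.0544). The hypoxia response median was 0.85 without WT day 4 array 1 (adjusted p = 7.09e-19). Its smallest p-values were those of Car9 (0.57, adjusted p = 0.0956) and Plod2 (0.59, adjusted p = 0.16), which passed without WT day 4 array 1 (0.0149 and 0.00535) and with array weights (0.0342 and 0.0281), Car9 also with the average of probe sets (0.0412). Secreted inflammatory factors had 2 of 36 negative and 0 positive, Mmp10 at -1.76 ± 0.30 and Igfbp5 at -1.05 ± 0.22, and 3 negative adjusted over the list alone. Their median was -0.50 (adjusted p = 0.012; adjusted p = 0.711 with an estimated correlation). Without WT day 4 array 1 the median of that list was 0.09 (adjusted p = 0.227), and with array weights it was -0.25 (0.261). The median of secreted inflammatory factors was -0.78 without WT day 4 array 2 and -0.91 without array 3 (5.13e-07), and the Igfbp5 call was lost in 6 of the 12 single omissions. The fibroblast and extracellular matrix list had 4 of 36 positive and 3 negative, against 7 and 4 adjusted over the list alone, with Timp3 at 0.87 ± 0.13 and Lum at -1.51 ± 0.27. The median was 0.14 (adjusted p = 0.0206; adjusted p = 0.694 with an estimated correlation). Its call was lost without WT day 4 array 1 (adjusted p = 0.0519) or 3 (0.08, 0.189), KO day 0 array 2 (0.0548) or KO day 4 array 2 (0.03, 0.481), or with array weights (0.131), and without WT day 4 array 2 the median of fibroblast and extracellular matrix genes was 0.22 (0.000128). Glycolysis genes did not pass (1 positive, 1 negative of 20; median 0.20, adjusted p = 0.0574) but passed without WT day 4 array 1 (0.53, adjusted p = 2.91e-11) or without WT day 0 array 2, KO day 0 array 1 or KO day 4 array 3 (0.0379, 0.0489 and 0.0463), and with array weights (5.19e-05), quantile normalization (0.028), median centring (0.0453) or the average of probe sets (0.0476). Macrophage markers did not differ in their changes (1 positive, 0 negative of 24; median -0.04, mean 0.05, adjusted p = 0.457), though without WT day 4 array 1 the list passed (median 0.15, adjusted p = 0.0372). The lists of p53 targets (median -0.01, mean 0.04), neural and Schwann cell markers (-0.02 and 0.10) and cartilage, bone and fat markers (-0.07 and 0.14) had a negative median and a positive mean and test, and none passed (adjusted p = 0.412, 0.297 and 0.527).

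**Figure D4:**
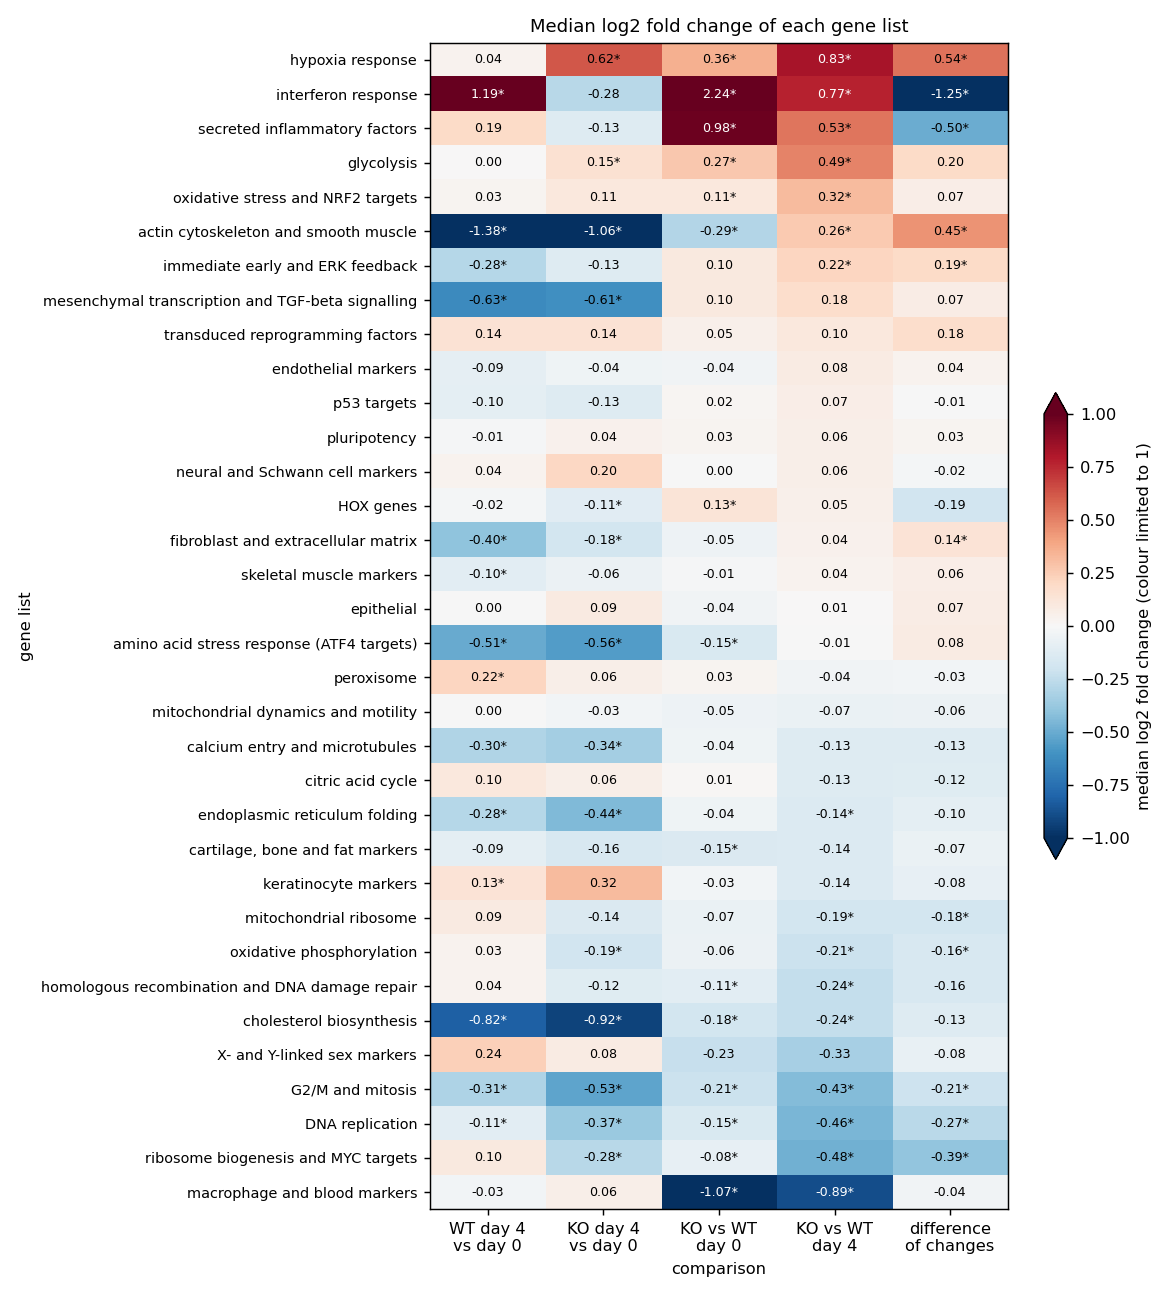
Median log2 change of each of the 34 gene lists (y axis) in each of the 5 comparisons (x axis), n = 3 arrays per group, with colour limited to 1 in either direction and an asterisk for an adjusted p under 0.05 in camera with the preset correlation. Interferon response genes had the medians 1.19 (WT day 4), 2.24 (KO against WT at day 0), 0.77 (at day 4) and -1.25 (difference).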

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

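The counts of other splits were planned. The second macrophage list and the test on fibroblast share were chosen only after the result was seen. So were the tests on macrophage RNA behind the interferon genes, array scaling, batch labels and WT day 4 array 1. Each group held 3 arrays, too few to test a single array against its group.

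The day 4 change differed between the genotypes, by the test of the difference itself in limma (adjusted p under 0.05), for 75 of the genes named. A negative value means that the change was lower in KO than in WT cells. The interferon-induced genes among them were Ifit1 (-3.74), Cmpk2 (-3.69), Oasl1 (-2.46), Irgm2 (-2.41), Mx2 (-2.40), Gbp7 (-2.13) and Ifit2 (-1.22), with Oas3 (1.07) in the other direction. Genes of growth, replication and division were Cad (-0.90), Mcm5 (-0.89), Nme1 (-0.78), Bop1 (-0.71), Chek1 (-0.70), Uhrf1 (-0.68), Lig1 (-0.58), Rpa2 (-0.57), Cdc20 (-0.56), Pola2 (-0.56), Cdc25c (-0.55), Nhp2 (-0.55), Ncapd2 (-0.54), Cdc45 (-0.53), Mybbp1a (-0.52) and Kif2c (-0.51). The respiratory chain genes were Uqcrq (-0.58), Ndufs8 (-0.48), Atp5g3 (-0.46) and Cyc1 (-0.44). Other negative differences were those of Slitrk6 (-2.52), Reg1 (-2.04), Cbr2 (-2.00), Clstn2 (-1.98), Mmp10 (-1.76), Prnd (-1.62), Lum (-1.51), Slc16a1 (-1.09), Slurp1 (-1.08), Igfbp5 (-1.05), Twist2 (-0.75), Krt16 (-0.75), Dcn (-0.70), Tuba1a (-0.67), Jund (-0.64) and Akr1c18 (-0.52). Cytoskeletal, matrix and ERK feedback genes with a positive difference were Prelp (2.58), Fhl5 (2.49), Tpm2 (1.29), Spry1 (1.26), Ankrd1 (1.18), Ccn1 (1.12), Timp3 (0.87), Etv5 (0.79), Acan (0.79), Dusp5 (0.73), Myh9 (0.62), Thy1 (0.58) and Cd44 (0.43). The remaining positive differences were those of Nppb (2.52), Lgr5 (2.31), Lurap1l (2.08), Map3k7cl (2.03), Elobl (2.02), Gjb2 (1.91), Fabp4 (1.87), Nqo1 (1.83), Perp (1.70), Slc2a3 (1.51), Trav9d-3 (1.43), Fcrls (1.17), Adssl1 (1.04), Txnip (1.00), Dlx5 (0.99), Laptm5 (0.88), Gsta4 (0.79) and Gclm (0.53). Of these, Fabp4, Oasl1, Irgm2, Mx2, Gbp7, Thy1, Dcn, Myh9, Rpa2, Mcm5, Lig1, Ncapd2, Cdc20, Cdc25c, Kif2c, Igfbp5, Atp5g3, Ndufs8, Cyc1 and Jund lost their call in at least 2 of the 12 single omissions, with adjusted p up to 0.117. A trended robust prior also ended the calls of Fabp4, Oasl1, Irgm2, Mx2 and Gbp7 (adjusted p from 0.0658 to 0.103), quantile normalization those of Atp5g3 (0.0505) and Cyc1 (0.0598), and the average of probe sets those of Etv5 (0.0613) and Jund (0.0998). Single omissions were not run for the differences of genes named under other comparisons alone, such as Prnd, Slc16a1 and Perp.

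By camera at the preset correlation, the day 4 change of 11 lists differed between the genotypes, and that of 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Their medians were -1.25 for interferon response, -0.50 for secreted inflammatory factors, -0.39 for ribosome biogenesis, -0.27 for DNA replication, -0.21 for G2/M and mitosis, -0.18 for the mitochondrial ribosome and -0.16 for oxidative phosphorylation. They were 0.54 for hypoxia response, 0.45 for actin and smooth muscle, 0.19 for immediate early and ERK feedback genes and 0.14 for the fibroblast list. Without WT day 4 array 1 the interferon response median was -0.77 (adjusted p = 1e-07), hypoxia response 0.85 (7.09e-19), actin cytoskeleton and smooth muscle 0.25 (0.000147) and immediate early and ERK feedback 0.38 (1.45e-05), and without WT day 4 array 3 that of G2/M and mitosis was -0.13 (0.0013). Array weights ended the calls of inflammatory factors (adjusted p = 0.261) and of the fibroblast list (0.131). Without WT day 4 array 1 the inflammatory median was 0.09 (adjusted p = 0.227); the fibroblast list did not pass without WT day 4 array 1 (0.0519) or 3 (0.189), KO day 0 array 2 (0.0548) or KO day 4 array 2 (0.481), nor hypoxia response without WT day 4 array 2 (0.0655) or 3 (0.0544).

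Probe sets without a single gene symbol, 17824 in number and outside every comparison above, also passed the threshold in limma: 1342 for WT day 4 against WT day 0, 2737 for KO day 4 against KO day 0, 226 for KO against WT at day 0, 1414 for KO against WT at day 4, and 100 for the difference of changes. What these probe sets measure was not analysed here.

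Other splits of the arrays were counted for each comparison. In each comparison of 2 groups, 1 of the 10 splits of the 6 arrays, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts in fits to the 6 arrays were 4097 for WT day 4 against WT day 0, 6903 for KO day 4 against KO day 0, 2453 for KO against WT at day 0 and 1923 for KO against WT at day 4, and the highest of the other splits gave 0 in each. For the difference of changes, 4 of 100 drawn splits of the genotype labels within days gave as many genes as the real one (877), and the highest other gave 982; these splits leave the genotype difference of each day in the data, so they do not show whether chance can be excluded.

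Macrophage and blood markers were lower in KO than in WT cells on both days, for example Lyz2 (9.29 in WT and 7.35 in KO cells at day 0), Cd68 (8.41 and 7.15), Fcer1g (8.40 and 6.10), C1qb (8.10 and 4.97) and Csf1r (6.89 and 5.39), where 0 of the 24 markers belong to another list and 11 lie above the median level of all genes. A higher fibroblast share would lower all other cell types alike. Of the endothelial, skeletal muscle, neural, keratinocyte, epithelial, and cartilage, bone and fat lists, 52 members lay above the median level. Their median at day 0 was -0.14 (quartiles -0.46 and -0.01), above the quartiles of the macrophage list (-1.67 and -0.68). Whether fibroblasts make these markers was not tested, so this cannot decide. The cartilage, bone and fat list was lower too (median -0.15, adjusted p = 0.016), while the epithelial list did not pass (-0.04, 0.0512). Fewer macrophages among the KO cells are a candidate explanation. Of a second list of 31 measured macrophage genes, 12 passed at day 0, all lower (median of all -0.61). Its 11 above the median level were all lower (median -0.72, and -0.91 at day 4). Less expression per macrophage, an effect of the genotype itself, would lower them too, so this list cannot decide and both stay open. No batch is named, so a difference between the preparations of the WT and the KO cells, which would alter the share of macrophages too, cannot be told apart from the genotype.

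Interferon and inflammatory genes were higher in KO than in WT cells at day 0. RNA of more macrophages in the KO arrays would bring macrophage markers with it, but their median at day 0 was -1.07, which argues against it. One scaling factor per array would move all its genes alike, which the opposite moves of the interferon list (quartiles 1.32 and 2.95) and the macrophage list (-1.67 and -0.68) argue against, while quantile normalization and centring on array medians, with an interferon median of at least 2.22 against 2.24, changed these values too little to decide anything. A preparation or culture batch stays open as a candidate explanation, since 0 label fields name a batch and none can be told apart from the genotype. An effect of the loss of Gdap1 stays open as well and was not tested apart from that.

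WT day 4 array 1 stood apart from the other WT day 4 arrays, with a hypoxia list mean 1.36 above theirs. A KO array carrying a WT label is argued against by its macrophage list mean, which lay 1.34 above the highest KO array, where the 6 KO arrays spanned 0.17. A day 0 array carrying a day 4 label is argued against by Klf4, which lay 2.87 above the highest day 0 array. A difference in total scale, as one factor for the array, is argued against by lists that moved apart: the mean lay above both other WT day 4 arrays by more than these differ for 8 of the 34 lists, hypoxia response among them, and under both for 5, among them cholesterol biosynthesis (-0.38, where the other two differ by 0.13). A difference in culture or handling of this sample could lie behind it, or a scale difference that varies with the level of a gene, and neither was tested.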

How the results depend on the processing

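Leaving out WT day 4 array 1 with KO day 4 array 2, and matching through any synonym, were chosen after the results were seen. The other alternatives were planned. A 2-fold minimum left 779 genes for WT day 4 against WT day 0, 834 for KO day 4 against KO day 0, 273 for KO against WT at day 0, 330 at day 4 and 179 for the difference of changes, by its construction. For KO against WT at day 0, array weights gave 2562 genes against 1242, a fit to those 2 groups 2453, and the omission of both arrays 2165. Single omissions gave 769 to 1936 there, the highest without WT day 4 array 1. For KO against WT at day 4, a fit to those 2 groups gave 1923 genes against 4596, and single omissions 2946 (without WT day 4 array 3) to 5929 (without WT day 4 array 1). The difference of changes had 877 genes, against 1852 with array weights, 503 with all probe sets, 2521 without both arrays, and 395 to 2140 with single omissions, the highest again without WT day 4 array 1. Array weights gave WT day 4 array 1 the lowest weight (0.31), then KO day 4 array 2 (0.59). An estimated correlation left 0 lists in each of the 5 comparisons, and single omissions gave 10 to 18 lists for the difference of changes. The correlation of the day 4 changes was 0.678 with all probe sets and 0.694 without both arrays, and 0.693 to 0.734 with single omissions, against 0.737. Apart from the 2-fold minimum, the cause of these moves was not tested. In WT day 4 against WT day 0, medians reversed without WT day 4 array 1 alone and without both arrays: inflammatory factors to -0.21 (adjusted p = 0.0229 and 0.0162), glycolysis to -0.23 (0.0201 and 0.0273) and hypoxia response to -0.45 (0.00042 and 0.00048). Without both arrays, actin and smooth muscle genes in KO against WT at day 4 reversed to -0.078 (adjusted p = 0.617), and without WT day 4 array 1 the inflammatory factors in the difference of changes reversed to 0.089 (0.227); the cause was not tested. Over single omissions these medians in WT day 4 against WT day 0 reached 0.641 for inflammatory factors and 0.12 for glycolysis (without WT day 4 array 3). They reached 0.24 for hypoxia response (without WT day 4 array 2), and -0.914 for inflammatory factors in the difference of changes (without WT day 4 array 3). The replicate number as a block gave 4931, 6647, 1181, 4417 and 801 genes in the 5 comparisons, and the deviations of arrays with the same number correlated between -0.06 and 0.18, so the numbers do not pair the samples. That block ended the calls of DNA replication in WT day 4 against WT day 0 (adjusted p = 0.0506) and of oxidative phosphorylation in KO day 4 against KO day 0 (0.052). Outside single omissions, results on named genes kept their side of the threshold in 3308 cases, lost a call in 43, gained one in 32 and reversed in 0. With single omissions these numbers were 4332, 263, 13 and 0. List results gave 1701, 93 (70 of them with an estimated correlation), 38 and 4 outside single omissions, and 1955, 28, 53 and 4 with them. A reversal was counted only where the main fit or the alternative gave a call, not in other results. Matching through any synonym changed 1 list call, that of glycolysis in KO day 4 against KO day 0 (median 0.14, adjusted p = 0.0541), because of the member it added. No scaling moved the median of all genes by more than 0.05. Signal over background limits genes under a level of 3.75, the 25th percentile, such as Gdap1.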

Other observations

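The tests on genes near Gdap1 and the lists below were chosen only after the result was seen, and the p-values of the lists, from camera and unadjusted, are no independent evidence for genes that had led the comparisons. Genes of adventitial fibroblasts were higher at day 4 in 10 of 14 cases in WT cells (1 lower, median 1.61, p = 1.21e-10, and p = 0.000444 with an estimated correlation) and in 10 in KO cells (0 lower, median 1.499, p = 1.98e-10 and p = 0.00048). Cd34 rose by 3.23 and 3.43, and Cd55 by 2.89 and 2.72. Squamous epithelial differentiation genes were higher at day 4 in 9 of 18 cases in WT cells (0 lower, median 0.83, p = 8.68e-09, and p = 0.0216 with an estimated correlation) and in 12 in KO cells (0 lower, median 1.02, p = 3.97e-09 and p = 0.0195). Imprinted growth genes were lower in KO than in WT cells in 5 of 14 cases on each day and higher in 0, with Mest at -2.03 and -1.69, Dlk1 at -1.36 and -1.64 and Plagl1 at -1.07 and -0.90 at day 0 and day 4. Their median was -0.22 at day 0 (p = 3.47e-05, and p = 0.127 with an estimated correlation) and -0.16 at day 4 (p = 0.0234 and p = 0.379).

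A linked DNA segment around Gdap1 from another strain, carried along with the deletion, is a candidate explanation for some genotype differences. Of the 40 genes nearest to Gdap1 on its chromosome, 5 passed in KO against WT at day 0 (12.5%, against 5.59% of all other genes; Fisher's exact test, two-sided, p = 0.071): Rdh10, Stau2, Pi15, Paqr8 and Tram2. The number of neighbours is too small for this share to decide, and the strains of the animals are not given in the sources used here.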
